A study of Homo sapiens with 6 samples.

How the data were processed

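Total RNA from Caco-2 cells in conventional or apical anaerobic culture was measured on 6 two-colour Agilent whole-genome expression arrays, each hybridised with 1 conventional and 1 apical anaerobic RNA. The labels give 12 RNAs, numbered 1 to 6 in each condition, and 3 arrays in each dye orientation. Arrays 1 to 4 were on 1 slide and arrays 5 and 6 on another. Each array was treated as 1 independent pair of cultures. The anaerobic and conventional numbers on an array differ except on array 1.

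Per the file headers, the deposited scanner files were made by Agilent Feature Extraction 10.10.1.1 and give spot intensity and local background intensity in each channel as median pixel values. Those files also hold processed intensity, which is background-subtracted and dye-normalized per the file headers, and a deposited log10 ratio of Cy5 over Cy3. The deposited value table holds log2 ratios, and the submitters' processing notes name limma and R 2.14.2 for it. Its background correction and normalization are not given in the sources used here. Set against the scanner ratios of bright spots, the deposited log2 values followed Cy5 over Cy3 on the 3 arrays with anaerobic RNA in Cy5 and were opposite on the other 3, with slopes of 0.983 to 0.994 and of -0.992 to -0.975, so they are ratios of anaerobic over conventional. The deposited table served as an alternative.

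Median spot intensities were background-corrected by normexp with an offset of 50 and normalised within arrays by loess in limma 3.58.1 under R 4.3.3. Control spots and spots that the scanner software marked as non-uniform or outlying had weight 0 in loess. Control spots were then left out. Unmarked spots of the same probe were averaged, which gave 41000 probes. Log ratios were turned so that positive values mean higher in apical anaerobic culture. A probe was tested when it was well above background, as judged by the scanner software, on at least 3 of 6 arrays in the channel of at least 1 condition, which left 30219 probes. Probes were given gene symbols by matching the RefSeq accessions in the scanner files, without version, to a table of RefSeq genes for GRCh38.p14. Of the 41000 probes, 23958 (58.4%) matched, for 16557 genes, and probes without a match entered the probe counts only. The scanner header names an older genome build (hg18), so no coordinates are given. Each gene was represented by its tested probe with the highest mean intensity, which gave 13675 genes. Among 4561 genes with several tested probes, 148 had probes that passed in opposite directions.

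The limma fit had a condition term and a dye term, which left 4 residual degrees of freedom. Its tests were two-sided, and adjusted p is the Benjamini-Hochberg value over 30219 probes, with a threshold of 0.05. The p-values treat the arrays as independent biological replicates. Errors are standard errors of the fitted log2 ratio, with a median over probes of 0.07. The scanner software marked 136 to 241 spots per array as non-uniform or outlying. Log ratios of the spike-in controls correlated with their nominal values at r = 0.986 to 0.995. Their slopes on the nominal values were 0.81 to 0.87, so measured spike-in log ratios were smaller than nominal. The folds given below were not corrected for this. Median signal per array was 95 to 127 in Cy3 and 109 to 181 in Cy5, against median local backgrounds of 50 to 73 and 58.5 to 61.

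Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists, with the estimated correlation, with fry and with an exact sign-flip test of the list median over 6 arrays as alternatives. The smallest two-sided p that test can give is 0.03125. For each list, the genes that passed were counted over all probes and adjusted over the list alone. The lists were HIF targets outside glycolysis, glycolysis, tricarboxylic acid cycle, oxidative phosphorylation, cholesterol, fatty acid synthesis and oxidation, tight junction, adherens junction and desmosome, enterocyte, goblet, Paneth and enteroendocrine cells, stem cell and Wnt targets, fibroblasts and leukocytes, mucins, unfolded protein response, ATF4, NRF2, NF-kappaB, interferon, heat shock, metallothioneins and zinc, carbonic anhydrases, iron, drug metabolism, DNA replication, p53, immediate early genes, clock, JmjC and other oxygenases, and cytosolic ribosomal proteins. There were 22 second memberships of a measured gene in another list. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule took the 10 largest increases and the 10 largest decreases among genes past the threshold with 1 direction on all 6 arrays and an official symbol, up to 3 members of each list past the threshold with the smallest adjusted p, and CA9, VEGFA, SLC2A1, LDHA, OCLN, TJP1, CLDN1, MUC2 and CDX2.

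The fit was tested on simulated data made from these arrays with 100 probes changed 1.5-fold and 100 changed 2-fold among 30219. It recovered 91 and 99 of them with 6 false calls. A simulated shift of 1 list was called and no other list was. The simulated noise was independent between probes and held no deviating array. The simulation therefore cannot test list calls where genes vary together. The alternatives were other background corrections and normalizations, other filters, no dye term, slide terms and slides alone, separate-channel fits with and without a replicate block, array weights, a trended robust prior, the deposited table, leaving out each array, stricter thresholds, probe averaging and other list tests. For the random slide effect and the separate-channel fits, lists were tested with cameraPR on the fitted statistics. Plots were drawn from the same values with matplotlib.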

Results

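Caco-2 cells, a human colon carcinoma line that forms a polarised enterocyte-like layer, were grown on porous inserts for 14 days and then held for 12 h in a co-culture chamber. In the conventional condition the chamber stood in a 5% CO2 incubator. In the apical anaerobic condition it stood in an anaerobic workstation, so that the apical face of the cells met a gas of 10% CO2 and 10% H2 in N2 while oxygen reached the cells from the basal side. RNA from 6 cultures of each condition was compared on 6 two-colour Agilent arrays, each carrying 1 RNA of each condition. The anaerobic RNA was labelled with Cy5 on 3 arrays and with Cy3 on the other 3. Between 26399 and 31672 probes per channel were well above background, and no spot was saturated. Log ratios of anaerobic over conventional correlated across probes at r = 0.60 to 0.91 between arrays, where probes are not independent replicates. Array 5 was the least like the others, with r = 0.74 against the mean of the remaining arrays, where the other arrays gave 0.83 to 0.90. The number of arrays limits the precision of every value.

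The comparison asked how the transcriptome of the cells differed between apical anaerobic and conventional culture. The conditions differed in apical oxygen, CO2, H2 and handling together, so no change below can be assigned to any of these alone. The strongest increases were in CXCR4, a chemokine receptor (37.3-fold), ANKRD1, a stress-responsive ankyrin repeat protein (26.2-fold), GDF15, a stress-induced cytokine (22.3-fold), DKK1, a secreted Wnt antagonist (17.1-fold), and ANKRD37, a HIF target (16.7-fold). Their log2 ratios were 5.22 ± 0.14, 4.71 ± 0.06, 4.48 ± 0.16, 4.10 ± 0.14 and 4.06 ± 0.11 (SE, n = 6 arrays, as for every gene below). ZFP36, which promotes decay of cytokine mRNAs, rose 14.4-fold, the transcription factors FOS and KLF6 rose 14.3-fold and 12.4-fold, the cytokine IL11 rose 11.2-fold and hexokinase HK2 rose by 3.46 ± 0.13 on the log2 scale. Decreases were smaller. G0S2, an inhibitor of triglyceride lipase, fell 5.36-fold (log2 ratio -2.42 ± 0.11), RFLNB, a filamin-binding protein, fell 5.20-fold (-2.38 ± 0.09) and MAT1A, a methionine adenosyltransferase, fell 4.51-fold (-2.17 ± 0.13). GPAM, which starts glycerolipid synthesis, was 4.21-fold lower, the chromatin protein HMGN2 3.99-fold, the peroxisomal membrane protein PXMP2 3.80-fold, the tRNA methyltransferase TRMT5 3.75-fold, the arrestin-like TXNIP 3.74-fold, the polyadenylation factor CSTF2T 3.74-fold and the alcohol dehydrogenase ADH4 3.71-fold. All 20 genes passed the limma test with adjusted p of 1.04e-04 or less and kept their direction on all 6 arrays. HMGN2 has many processed pseudogenes that its probes could also bind, and its value is uncertain for that reason. A second probe was weaker for GPAM (log2 ratio -0.17, adjusted p = 0.0907), for CSTF2T (-0.62) and for RFLNB (-0.72). Other named genes had another probe that passed in the same direction with a fold differing by more than 1.5 times from the printed one. The log2 ratios of these probes were 2.37 for HK2, 1.84 for TJP1, 1.39 for PDK1, 1.19 for NDRG1, 0.80 for TNFAIP3, 0.69 for SC5D, 0.19 for MYC, -1.25 for HSPA8 and -1.41 for HMGN2.

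**Figure D1:**
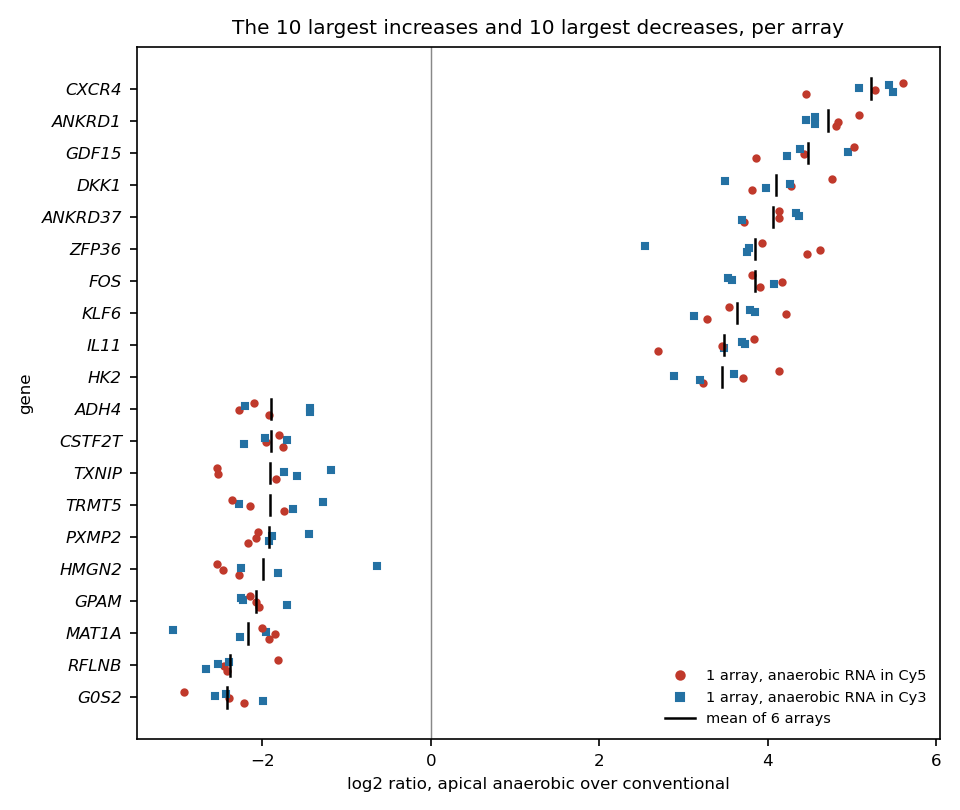
Log2 ratio of apical anaerobic over conventional (horizontal axis) for the 10 genes with the largest increase and the 10 with the largest decrease (vertical axis); each point is 1 of 6 arrays, coloured by the dye that carried the anaerobic RNA, and the black bar is the mean of 6 arrays. CXCR4 lies at 5.22 and G0S2 at -2.42, and in each of the 20 genes all 6 arrays fall on the same side of 0.

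Of 13675 genes tested, 7549 (55.2%) passed an adjusted p of 0.05 in limma, with 3254 higher and 4295 lower in apical anaerobic culture. Large changes were mostly increases. At least 2-fold, 639 genes were higher and 398 lower, at least 4-fold 106 were higher and 4 lower, and at least 8-fold 24 were higher and none lower. Over probes, 15411 of 30219 passed, of which 7448 were higher and 7963 lower. Of the probes that passed, 11911 (77.3%) had the same direction on all 6 arrays, a share raised by their selection on the same arrays. The median log2 ratio of all probes was 0.02, a value that normalization within arrays sets near 0. A shift shared by most probes would therefore not show. The counts of higher and lower genes and probes are relative to this centring. With at least 1.5-fold as an added condition, 5632 probes passed. No probe passed the same threshold for the dye term in limma. At an unadjusted p under 0.05, 5818 probes (19.3%) did. That is a larger share than the 0.05 expected without any dye effect. Arrays of the same dye orientation correlated at a median r of 0.83 (0.68 to 0.91 over 6 pairs). Arrays of opposite orientation correlated at 0.75 (0.60 to 0.85 over 9 pairs). Both results go with a dye effect in part of the probes, although no single probe passed.

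**Figure D2:**
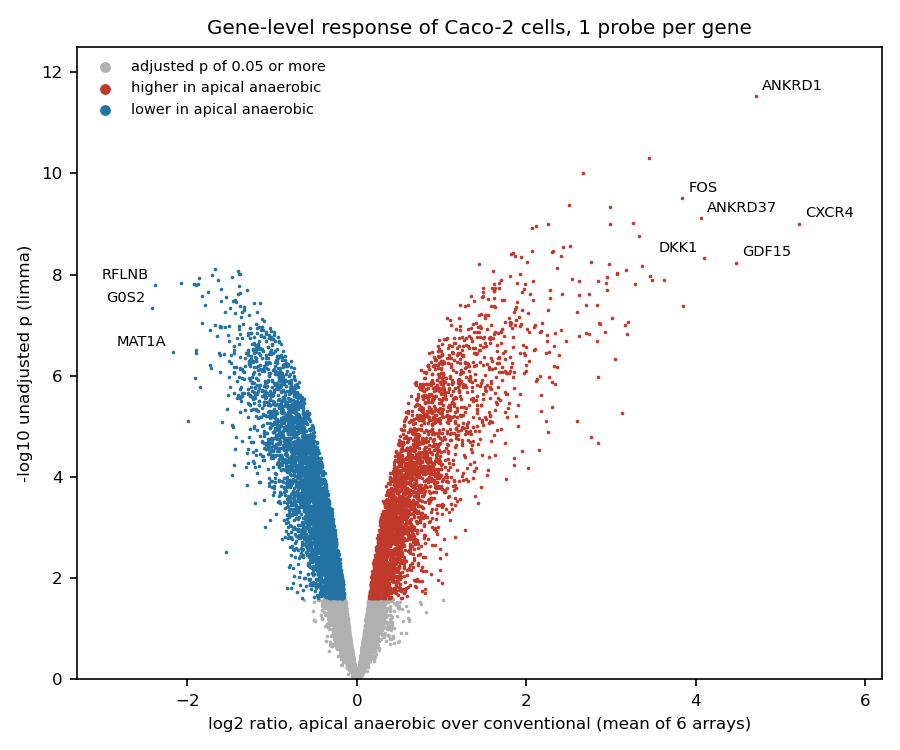
Log2 ratio of apical anaerobic over conventional (horizontal axis, mean of 6 arrays) against the negative log10 of the unadjusted limma p (vertical axis) for 13675 genes, 1 probe per gene; red and blue mark the 3254 higher and 4295 lower genes with an adjusted p under 0.05. The right arm, with CXCR4, ANKRD1 and GDF15, reaches further from 0 than the left.

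Immediate early genes, which are transcribed within minutes of a growth or stress signal, formed the group with the largest median increase among the 30 gene lists. Of 24 measured, 23 rose and none fell, both over all probes and adjusted over the list alone, and the median log2 ratio was 2.68. Besides FOS, the phosphatases DUSP4 and DUSP6, which dampen MAP kinase signalling, rose 6.35-fold (log2 ratio 2.67 ± 0.05) and 9.59-fold (3.26 ± 0.09). The camera test of this list against all other genes gave adjusted p = 1.07e-12, and adjusted p = 0.0856 with an estimated correlation. Among NF-kappaB target and cytokine genes, 18 of 28 rose and 2 fell over all probes, with the same counts adjusted over the list alone and a median log2 ratio of 0.77 (camera adjusted p = 1.44e-05, and adjusted p = 0.368 with an estimated correlation). The members with the smallest adjusted p were BIRC3, an inhibitor of apoptosis (6.71-fold, 2.75 ± 0.12), LTB, a membrane-bound cytokine (5.32-fold, 2.41 ± 0.13), and TNFAIP3, a feedback inhibitor of NF-kappaB (3.67-fold, 1.87 ± 0.09).

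Of 30 HIF target genes outside glycolysis, 24 rose and 3 fell over all probes, 24 rose and 5 fell adjusted over the list alone, and the median log2 ratio was 1.21 (camera adjusted p = 4.7e-09, and adjusted p = 0.0856 with an estimated correlation). The histone demethylase KDM3A rose 5.66-fold (SE 0.06 on the log2 scale), NDRG1 rose 3.54-fold (log2 ratio 1.82 ± 0.06) and the angiogenic factor VEGFA rose 3.57-fold (1.84 ± 0.10). CA9, the carbonic anhydrase often used as a marker of hypoxia, was not well above background on any array in either condition and was not tested. Among 24 JmjC demethylases and other oxygenases that use 2-oxoglutarate, 15 rose and 2 fell over all probes, 16 rose and 2 fell adjusted over the list alone, and the median was 0.46 (camera adjusted p = 2.08e-04, and adjusted p = 0.166 with an estimated correlation). KDM6A and KDM5B in this list rose 2.80-fold and 2.32-fold.

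Glycolysis was called higher, and oxidative phosphorylation and the tricarboxylic acid cycle were called lower. In the glycolysis list, 15 of 25 genes rose and 2 fell over all probes, 17 rose and 2 fell adjusted over the list alone, and the median log2 ratio was 0.42 (camera adjusted p = 6.97e-06, and adjusted p = 0.0856 with an estimated correlation). The glucose transporters SLC2A3 and SLC2A1 rose 7.95-fold (2.99 ± 0.07) and 4.82-fold (2.27 ± 0.16), PDK1, which blocks pyruvate entry into the citric acid cycle, 5.72-fold (2.52 ± 0.08), enolase ENO2 4.21-fold (2.07 ± 0.06) and lactate dehydrogenase LDHA 3.50-fold (1.81 ± 0.07). Of 62 oxidative phosphorylation genes, 49 fell and none rose over all probes, 52 fell and 1 rose adjusted over the list alone, and the median was -0.47 (camera adjusted p = 3.22e-09, and adjusted p = 0.0856 with an estimated correlation). The complex I subunits NDUFB2, NDUFS6 and NDUFB10 were 2.91-fold (-1.54 ± 0.07), 2.52-fold (-1.33 ± 0.06) and 2.03-fold (-1.02 ± 0.05) lower. In the tricarboxylic acid cycle, 12 of 22 genes fell and 1 rose, with the same counts adjusted over the list alone and a median of -0.31 (camera adjusted p = 0.0342, and adjusted p = 0.412 with an estimated correlation). Fumarase FH (1.76-fold), pyruvate dehydrogenase PDHA1 (1.48-fold) and succinate dehydrogenase SDHA (1.40-fold) were among the lower members, although a second SDHA probe did not pass (log2 ratio -0.17, adjusted p = 0.0787). The median of this list was at percentile 6.35 of 10000 random lists matched on intensity, within their central 95% of -0.37 to 0.22. Its call was lost with a normexp offset of 16 (adjusted p = 0.0524), on slide 1 alone (0.0673) and with the stricter filter on dim probes (0.0518), and held in the other 19 of 22 settings (from 0.00825).

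In cholesterol synthesis and uptake, 17 of 26 genes rose and 3 fell over all probes, 18 rose and 3 fell adjusted over the list alone, and the median log2 ratio was 0.62 (camera adjusted p = 2.7e-04, and adjusted p = 0.424 with an estimated correlation). STARD4, a sterol carrier, rose 6.06-fold (2.60 ± 0.12) and the sterol desaturase SC5D 3.01-fold (1.59 ± 0.07), while the sterol reductase TM7SF2 fell 2.56-fold (-1.36 ± 0.06). Fatty acid oxidation and ketogenesis had 6 genes higher and 12 lower of 24 over all probes, 6 and 13 adjusted over the list alone, and was not called (median -0.20, camera adjusted p = 0.197). Its members included the isomerase ECI1, 1.99-fold lower, the carnitine carrier SLC25A20, 2.41-fold lower, and the lipid droplet protein PLIN2, 3.37-fold higher. Fatty acid synthesis, with 5 genes higher and 4 lower of 15 over all probes and adjusted over the list alone, was not called either (median 0.08, camera adjusted p = 0.388). SREBF1, ME1 and ELOVL5 in that list rose 1.94-fold, 1.64-fold and 1.57-fold.

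More genes of the epithelial junctions rose than fell. Of 27 tight junction genes, 14 rose and 2 fell over all probes, 17 rose and 4 fell adjusted over the list alone, and the median log2 ratio was 0.30 (camera adjusted p = 3.18e-04, and adjusted p = 0.166 with an estimated correlation). Occludin OCLN rose 3.72-fold (1.90 ± 0.08), claudin CLDN4 3.28-fold (1.71 ± 0.09), the polarity protein PARD6B 3.07-fold (1.62 ± 0.07) and ZO-1, encoded by TJP1, 1.68-fold (0.75 ± 0.11, adjusted p = 9.56e-04). The brighter probe of CLDN1 did not pass (0.10 ± 0.09, adjusted p = 0.381), although a second CLDN1 probe did (1.13, adjusted p = 3.07e-05), and without array 5 the brighter probe passed as well (0.18, adjusted p = 0.0466, where the 22 settings ranged up to 0.873). Of 20 adherens junction and desmosome genes, 14 rose and 3 fell over all probes and adjusted over the list alone (median 0.30, camera adjusted p = 0.00223, and adjusted p = 0.166 with an estimated correlation). The actin linker VCL rose 2.25-fold, the desmosomal PPL 2.07-fold and the cadherin DSG2 2.01-fold.

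Camera called none of the lists of intestinal differentiation markers, while fry called the goblet, Paneth and enteroendocrine list downward (adjusted p = 0.00535) and the mucin (0.00496) and stem cell (0.0289) lists upward. The enterocyte and brush border list held 7 higher and 11 lower genes of 35 over all probes and adjusted over the list alone (median -0.02, camera adjusted p = 0.852), with KRT20 4.47-fold higher, the actin regulator EPS8 2.36-fold higher and the fatty acid binding protein FABP1 1.72-fold lower. The goblet, Paneth and enteroendocrine list held 2 higher and 3 lower genes of 16, and none higher and 3 lower adjusted over the list alone (median -0.02, camera adjusted p = 0.866). The lower genes were TFF3 (1.73-fold), ZG16 (1.67-fold) and CHGB, whose signal was well above background on only 3 of 6 arrays in the anaerobic channel, so that no fold is given. Among mucins and trefoil factors, 3 of 9 were higher and 2 lower over all probes and adjusted over the list alone (median 0.05, camera adjusted p = 0.489). The membrane mucins MUC13 and MUC17 rose 2.26-fold and 2.23-fold, and TFF2 fell 1.54-fold. A second MUC17 probe did not pass (log2 ratio 0.07, adjusted p = 0.345). The secreted mucin MUC2 (0.42 ± 0.20, adjusted p = 0.121) and the intestinal transcription factor CDX2 (0.26 ± 0.11, adjusted p = 0.095) did not pass. MUC2 passed with array quality weights (0.52, adjusted p = 0.0432, the settings ranging up to 0.342), and CDX2 passed without array 5 (0.34, adjusted p = 0.0349), without array 6 (0.35, adjusted p = 0.0427) and in 3 further settings, with adjusted p of 0.00794 to 0.348 over 22. Among intestinal stem cell and Wnt target genes, 6 of 17 were higher and 7 lower over all probes and adjusted over the list alone. The median of this list was -0.07, its mean 0.25 and its camera direction upward, without a call (adjusted p = 0.81). DKK1 belongs to this list and has its largest log2 ratio, 4.10, which raises the mean. MYC rose 2.89-fold on its brighter probe, and ASCL2, a stem cell transcription factor, fell 2.74-fold. Markers of fibroblasts and leukocytes, cell types the culture should lack, had 3 of 14 higher over all probes and none adjusted over the list alone (median 0.08, camera adjusted p = 0.325). The 3 were THY1 (1.22-fold), CD68 (1.25-fold) and LUM (1.44-fold), and each lost its call when single arrays were left out.

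The DNA replication and mitosis list was called lower. Of 39 genes, 21 fell, 2 rose and 16 did not pass over all probes, with the same counts adjusted over the list alone and a median log2 ratio of -0.31 (camera adjusted p = 0.00217, and adjusted p = 0.47 with an estimated correlation). PCNA, the polymerase clamp, was 2.93-fold lower (-1.55 ± 0.07), the helicase subunits GINS2 and MCM3 2.72-fold and 2.17-fold. These are replication genes, and mitotic members were mixed. CCNB1 and PLK1 fell 1.36-fold and 1.24-fold, whereas CDK1, AURKA, AURKB and BUB1 did not pass. The 2 higher genes were CCNA2 (1.19-fold) and TTK (1.43-fold). Among p53 target genes, 8 of 18 were higher and 5 lower over all probes and adjusted over the list alone, without a call (median 0.22, camera adjusted p = 0.0668), and PLK3 and BTG2 rose 7.74-fold and 2.53-fold. The p53 list was called without array 6 (adjusted p = 0.038) and in 3 other settings, over a range of 0.0341 to 0.133. Of 20 clock genes, 13 rose and 1 fell over all probes, 13 rose and 2 fell adjusted over the list alone, and the median was 0.36 (camera adjusted p = 3.77e-04, and adjusted p = 0.13 with an estimated correlation). The repressors NR1D1, PER1 and NFIL3 rose 4.99-fold (2.32 ± 0.08), 3.10-fold (1.63 ± 0.07) and 2.80-fold (1.49 ± 0.06). The cytosolic ribosomal protein list was called higher by camera, although 40 of its 50 genes did not pass, with 10 higher and none lower over all probes, 3 higher adjusted over the list alone and a median of 0.16 (camera adjusted p = 8.91e-04, and adjusted p = 0.0856 with an estimated correlation). RPS9, RPL22 and RPL37 were 1.52-fold, 1.47-fold and 1.37-fold higher, values that are uncertain because ribosomal protein genes have many near-identical pseudogenes. The medians of this list were 0.26, 0.37 and 0.34 on the arrays with anaerobic RNA in Cy5 and 0.02, 0.06 and 0.07 on those with it in Cy3, and its call was lost with the scanner software's processed signals (adjusted p = 0.0723) and held in the other 21 of 22 settings.

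Stress and homeostasis lists held genes that changed in each direction and were not called by camera. Heat shock proteins had 5 genes higher and 12 lower of 21 over all probes and adjusted over the list alone (median -0.36, adjusted p = 0.0794), with the chaperones HSPA8, HSP90AA1 and DNAJA1 lower by 3.61-fold, 2.24-fold and 2.00-fold, and the list was called without array 4 (adjusted p = 0.021) and in none of the other settings (up to 0.304). HSPA8 and HSP90AA1 also have pseudogenes, so their values are uncertain. In the unfolded protein response, 7 of 23 were higher and 10 lower over all probes and adjusted over the list alone (median 0.04, adjusted p = 0.98). PPP1R15A, which restores translation after stress, rose 5.13-fold, whereas the endoplasmic reticulum proteins CRELD2 and SDF2L1 fell 2.95-fold and 2.73-fold. ATF4 target and amino acid synthesis genes counted 13 higher and 8 lower of 27 over all probes and adjusted over the list alone (median 0.28, adjusted p = 0.105), among them the mTORC1 inhibitor DDIT4 (5.07-fold higher), STC2 (3.00-fold higher) and the serine synthesis enzyme PSAT1 (2.56-fold lower). NRF2 targets counted 10 higher and 7 lower of 23 over all probes, 10 and 8 adjusted over the list alone (median 0.01, adjusted p = 0.489), with NFE2L2, TXNRD1 and ABCC2 up 2.66-fold, 2.43-fold and 2.06-fold. Interferon-stimulated genes counted 7 higher and 6 lower of 26 over all probes and adjusted over the list alone (median -0.04, adjusted p = 0.98), and PSMB9, IFIH1 and TAP1 fell 1.68-fold, 1.84-fold and 1.35-fold.

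Transport and metal lists were not called by camera either. Drug metabolism and transport had 7 genes higher and 9 lower of 25 over all probes, 9 and 9 adjusted over the list alone (median 0.06, adjusted p = 0.98). TIPARP, a target of the aryl hydrocarbon receptor, rose 9.06-fold (3.18 ± 0.12) and the receptor AHR itself 3.20-fold. In the same list CYP1A1 did not pass (log2 ratio 0.06, limma adjusted p = 0.797), and CYP1A2 and CYP1B1 rose 1.34-fold and 1.43-fold. Activity of the receptor was not tested. The glutathione transferase GSTA2, which has near-identical paralogs and is uncertain for that reason, fell 2.75-fold. Carbonic anhydrases and acid-base transporters had 5 higher and 3 lower of 17 over all probes and adjusted over the list alone (median 0.01, adjusted p = 0.489). The lactate exporter SLC16A3 rose 2.15-fold, the sodium-proton exchanger SLC9A2 rose 1.84-fold and CA4 fell 1.68-fold. Iron uptake and storage had 3 higher and 2 lower of 18 over all probes, 2 and 2 adjusted over the list alone. The median of the iron list was -0.05, its mean 0.03 and its camera direction upward (adjusted p = 0.81), with IREB2 1.86-fold higher and STEAP3 and ACO1 1.77-fold and 1.38-fold lower. A second ACO1 probe did not pass (log2 ratio -0.13, adjusted p = 0.211). Metallothioneins and zinc transporters had 3 higher and 1 lower of 15 over all probes and 1 of each adjusted over the list alone (median 0.42, adjusted p = 0.101), and their medians ranged from -0.64 on array 5 to 1.32 on array 4. Without array 5 the median was 0.71 and the list was called (adjusted p = 0.0178, the settings ranging up to 0.164), with 10 genes higher and 1 lower. Genes of this list varied together, with an estimated correlation of 0.40 on all arrays, so these genes are not independent. With that correlation, camera on all arrays gave adjusted p = 0.636. Whether probes of related metallothionein genes share signal was not tested. The zinc exporter SLC30A1 rose 2.76-fold, and SLC39A4 (1.16-fold higher) and SLC39A5 (1.35-fold lower) lost their calls when single arrays were left out.

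**Figure D3:**
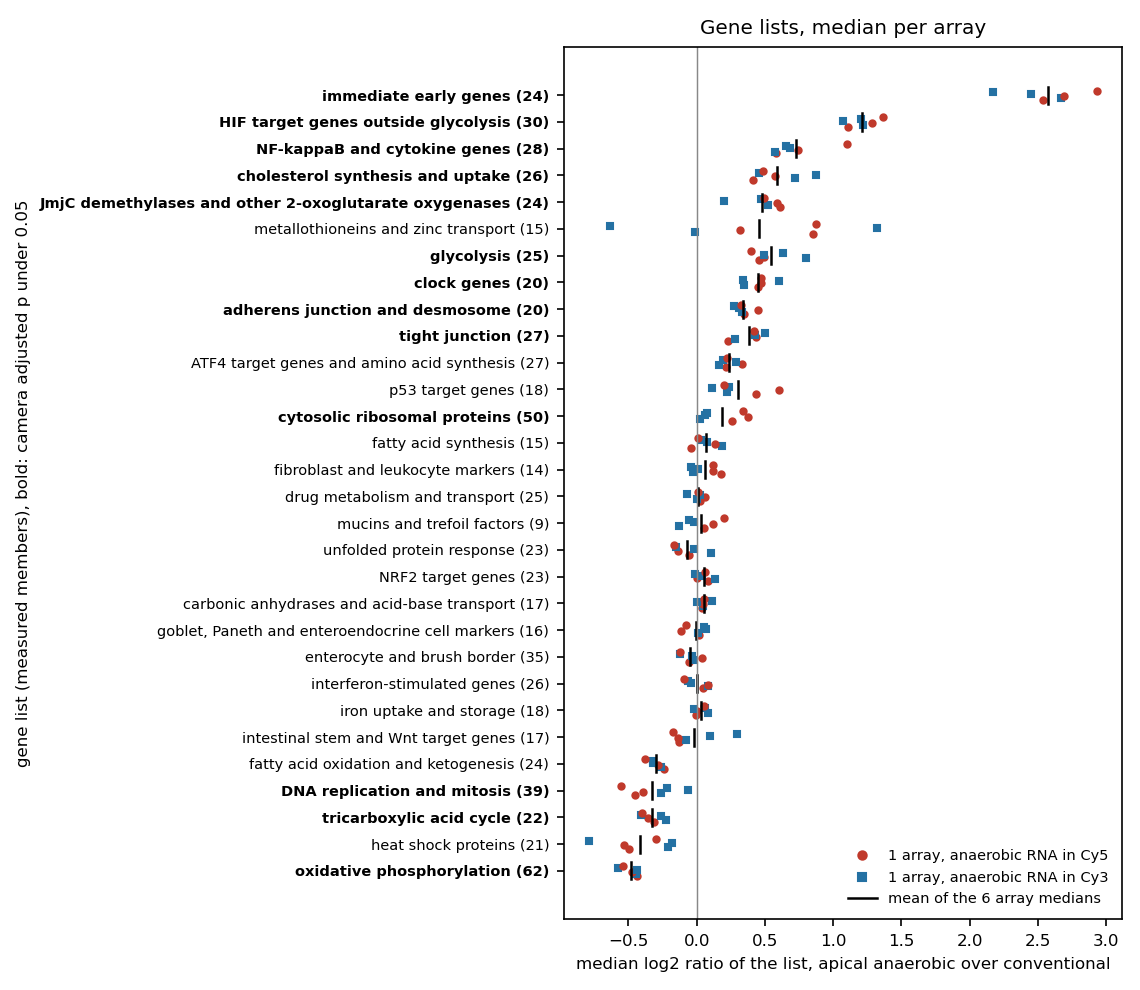
Median log2 ratio of apical anaerobic over conventional (horizontal axis) for each of 30 gene lists (vertical axis, with the number of measured genes); each point is 1 of 6 arrays, coloured by the dye that carried the anaerobic RNA, the black bar is the mean of the 6 array medians, and bold names have a camera adjusted p under 0.05 at the preset correlation. Immediate early genes lie highest on every array, between 2.17 and 2.93, and the oxidative phosphorylation list lies between -0.57 and -0.44.

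Camera called 13 of the 30 lists at a preset correlation of 0.01, 10 upward and 3 downward. With correlations estimated from the 6 arrays it called none (9 lists at an unadjusted p under 0.05), so no list call held under that stricter test, while fry, which does not compare a list with other genes, called 23. Arrays 5 and 6 were on a second slide. Of 15641 probes that passed in limma on slide 1 alone, 91.3% had the same sign on slide 2, a comparison added after the data were seen.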

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

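Of the tests below, those of array 5, the split of arrays with a dye term and the handling of immediate early genes were chosen only after the result was seen. Among the 30 lists and the named genes, 142 sets of 6 array values were searched for a single array far from the other 5, and 8 had one, where chance gives about 7.1. Among lists, the NF-kappaB and cytokine median was 1.11 on array 6 and 0.58 to 0.75 elsewhere, and the JmjC and 2-oxoglutarate oxygenase median was 0.20 on array 4 and 0.47 to 0.61 elsewhere. IL11 had a log2 ratio of 2.70 on array 1 and 3.45 to 3.84 elsewhere. RFLNB stood at -1.81 on array 6, against -2.67 to -2.39 on the others. MAT1A stood at -3.06 on array 5, against -2.26 to -1.85. EPS8 was 0.51 on array 5 and 1.26 to 1.59 on the others. PER1 was 1.96 on array 3 and 1.44 to 1.61 on the others. VEGFA was 1.24 on array 5 and 1.84 to 2.12 on the others. The direction was the same on all 6 arrays in each of these 8 sets.

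Array 5 carried 3 of these values and correlated least with the others. Its r with the mean of the other arrays was 0.74 (0.7409), which a swapped dye label would have made negative. Among the brightest probes, those in the top 25% of mean intensity, its r was again 0.74 (0.7408), while the lowest of the other arrays reached 0.86, which argues against weak signal as the source. Array 5 also had the lowest median Cy5 signal, 109, where the other arrays had 146 or more. On bright spots its deposited ratios correlated with the scanner ratios at r = -0.864. The size of that r was at least 0.9756 on every other array. Its 2 cultures may have differed from the other pairs, or an unrecorded handling step may have. A technical fault of the array is also open, and with 1 array of these RNAs these cannot be told apart. Without array 5, 16171 probes passed in limma, compared with 15411 on all arrays.

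The increase of immediate early genes was set against technical explanations because these genes respond quickly to handling. Dye bias was argued against by the lowest of the 6 array medians, 2.17, which lay far above 0 in both dye orientations. One array or slide as the source was argued against by a lowest median of 2.60 when any array was left out or either slide was taken alone. Handling in the anaerobic workstation or at lysis remained open: all anaerobic cultures were handled in the workstation and all conventional ones outside it, so the list median of 2.68 could come from the gas or from the handling, and these cannot be told apart. The same limit holds for every other gene and list compared here. No biological explanation beyond the culture condition was tested.

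The decrease of oxidative phosphorylation genes was set against an intensity-dependent bias. Its median of -0.47 was at percentile 0 of 10000 random lists matched on intensity, whose central 95% ran from -0.29 to 0.09, and with the processed signals of the scanner software the percentile was again 0. The same comparison put cytosolic ribosomal proteins at percentile 99.6. The highest array median of the oxidative phosphorylation list was -0.44, so dye orientation did not turn it. These values argue against both explanations. The random lists were drawn gene by gene, whereas genes of this list had an estimated correlation of 0.05, so percentile 0 does not exclude an intensity-dependent bias. A lower level of these transcripts in apical anaerobic culture remains a hypothesis, found and tested on the same arrays.

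The count of probes past the threshold was compared with other arrangements of the arrays. In the fit without a dye term, 1 of the 32 sign patterns, the real one, gave as many as 13954 probes. The highest other pattern gave 0 in limma (7426 at an unadjusted p under 0.05). A share of 3.125% is the smallest that 32 patterns can give, so this argues against chance without excluding it. Other patterns also turn the real difference into scatter, which lowers their counts. In the fit with a dye term, the 10 splits are too few for a share under 0.05. The real split, 1 of the 10, gave 15411 probes and the highest other 0 in limma (1186 at an unadjusted p under 0.05).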

How the results depend on the processing

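No alternative below was chosen after the data were seen, except that the fit without array 5, planned among those that leave out 1 array, was also singled out later, and that the direction of slide 1 calls on slide 2 was added. The count of probes past the threshold ranged from 12336 with median centring to 17951 with the processed signals over the settings that change processing or model, and from 12316 (without array 3) to 16171 (without array 5) when 1 array was left out, against 15411. In none of these settings did a probe that passed in the fit to all arrays pass in the opposite direction. With at least 1.5-fold required, 5632 probes passed, 2926 higher and 2706 lower. Median centring gave 43.7% of calls higher, against 48.3%. The list tests were the result that depended most on a choice: of 30 lists, camera called 13 at the preset correlation, 12 to 14 across the other processing settings and 13 to 14 when 1 array was left out. With an estimated correlation camera called 0 (9 at an unadjusted p under 0.05, smallest adjusted p 0.0856), the exact sign-flip test called 0 (18 at an unadjusted p under 0.05, smallest adjusted p 0.0521) and fry called 23, 16 upward and 7 downward. With 6 arrays the sign-flip test gives no p under 0.03125, and the estimated correlations rest on 4 residual degrees of freedom. Fry called drug metabolism downward although its median was 0.06. CD68 was -0.0174 on slide 2 alone, which reversed it; slide 2 has 2 arrays and no test, and the cause was not tested. Calls of CD68, LUM, THY1, SLC39A4, SLC39A5, RPL22 and RPL37 were lost in 1 or more settings, and no other named gene that passed lost its call where it was tested. CHGB was removed by the filter that requires signal in both channels of all 6 arrays and has no value there. The replicate numbers gave no sign of pairing the cultures. Deviations of same-numbered RNAs correlated at r = -0.34 to 0.11 apart from number 3, whose RNAs shared an array (0.61). Of 12 channels, 2 correlated best with their own number. The 2 channels of a spot had a fitted correlation of 0.55. The other same-numbered RNAs lay on different arrays, so a weak pairing could be hidden. With the numbers as a replicate block 15390 probes and 14 lists passed, against 16098 and 13 in the same fit without the block. Relative to that fit, the block added calls for the metallothionein list (adjusted p = 0.0178), CDX2 (0.0335) and THY1 (0.0514 without the block), and changed the call of no other list or named gene. Weak signal limits what can be tested: 30219 of 41000 probes passed the filter, and CA9 did not.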

Other observations

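The gene families in these paragraphs, and their tests, were chosen only after the data were seen, except that the intensity test of the mitochondrial ribosomal genes was set before its result. Of 49 MRPL genes, 41 fell and none rose (median log2 ratio -0.59, camera adjusted p = 1.11e-07, and adjusted p = 0.374 with an estimated correlation), and of 28 MRPS genes, 22 fell and 1 rose (median -0.55, camera adjusted p = 1.88e-04, and adjusted p = 0.386 with an estimated correlation). MRPL12 and MRPS7 were 1.74-fold and 1.85-fold lower. Nudix hydrolases of the NUDT family (13 of 18 lower and 2 higher, median -0.45), tRNA methyltransferases of the TRMT family (11 of 15 lower and 1 higher, -0.36), intraflagellar transport genes of the IFT family (11 of 17 lower and none higher, -0.25) and zinc finger genes of the ZNF family (153 of 350 lower and 49 higher, -0.13) were also called downward, although most ZNF genes did not pass as lower, with camera adjusted p between 0.012 and 0.044, and adjusted p of 0.374 to 0.445 with an estimated correlation. Proteasome subunit genes, PSMA to PSMG, formed 1 further set with 36 of 47 lower and 3 higher (median -0.41, camera unadjusted p = 7.15e-07, and p = 0.0187 with an estimated correlation). Krüppel-like factors rose in 10 of 16 cases with none lower (median 0.66), TNF receptor genes of the TNFRSF family in 9 of 16 with 1 lower (0.37), KDM demethylases in 9 of 16 with 1 lower (0.36), RPL genes in 15 of 53 with 1 lower (0.16) and keratins in 12 of 28 with 4 lower (0.15), with camera adjusted p between 3.46e-04 and 0.0367, and adjusted p of 0.386 to 0.418 with an estimated correlation. KLF4 was 2.51-fold higher, and the receptors TNFRSF12A and TNFRSF21 were 3.28-fold and 3.65-fold higher. Some of these genes are also in lists already described, so those calls are not independent: many KDM and RPL genes, KLF2, KLF4 and KLF6 among immediate early genes, TNFRSF10B among p53 targets, KRT20 among enterocyte genes and PSMB9 among interferon-stimulated genes.

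Several single genes outside the lists, named here after their values were seen and not tested as a group, had the following values. The epidermal growth factor receptor ligand AREG rose 9.77-fold (log2 ratio 3.29 ± 0.13), EREG 7.23-fold (2.85 ± 0.11) and HBEGF 3.12-fold (1.64 ± 0.12), and each was higher on 6 of 6 arrays. The vasoconstrictor peptide EDN1 rose 10.9-fold (3.44 ± 0.06), and the urokinase receptor PLAUR rose 8.41-fold (3.07 ± 0.11). HIF1A rose 1.51-fold (0.59 ± 0.06), and EPAS1 did not pass (-0.07 ± 0.07, adjusted p = 0.474). ARRDC4, a relative of TXNIP, fell 3.33-fold (-1.73 ± 0.11).

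The hypothesis that further gene families moved together was tested with camera on 90 families of 15 or more genes that share a symbol prefix. Of these, 11 passed an adjusted p of 0.05, 5 higher and 6 lower, which is consistent with the hypothesis at the preset correlation, and 0 passed with an estimated correlation (8 at an unadjusted p under 0.05). The directions of the 11 families and of the proteasome set were the same under all 7 background corrections, scalings and tables compared, but their sizes were not. The medians ranged from 0.37 to 0.77 for TNFRSF, 0.56 to 0.95 for KLF, 0.13 to 0.28 for keratins, 0.10 to 0.26 for RPL, -0.55 to -0.25 for IFT and -0.27 to -0.13 for ZNF genes. For the MRPL and MRPS genes as 1 set, the median of -0.56 was at percentile 0 of 10000 random lists matched on intensity. The random lists were drawn gene by gene, and this set was chosen after its values were seen. Percentile 0 therefore argues against an intensity-dependent bias of the arrays as the source without excluding it. Among 10663 tested probes without a gene symbol, 4668 passed in limma, 2358 higher and 2310 lower.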
